A study of Mus musculus with 6 samples.

How the data were processed

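RNA was measured by sequencing of polyadenylated transcripts from the distal mandible of single mouse embryos at embryonic day 10.75. The series has 6 libraries, written here as 3 libraries labelled mutant and 3 labelled control, with 1 of each from each of 3 litters. Both labels carry Hand2-Cre, a Cre recombinase expressed under control of Hand2 regulatory sequence, together with a Rosa26 mTmG reporter, which turns cells green after recombination. Per the labels, mutants are homozygous for floxed Msx1 and floxed Msx2, whereas controls are heterozygous for floxed Msx1 and homozygous for floxed Msx2. The labelled genotypes therefore differ at Msx1 only.

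For each library the authors deposited 1 value per gene in TPM (transcript abundance scaled to a fixed total per library), for 21827 genes. The submitters' processing notes list Salmon 1.5.2, DESeq2 and the mm10 build, without their roles or settings. The version of DESeq2, the annotation release, the way that transcripts were joined into genes and any filter are not given in the sources used here. The TPM of the listed genes summed to between 716208 and 735601 per library, so that part of each TPM total lies in genes that are not listed. TPM keep no record of sequencing depth, and the depth of each library is unknown. Precision is therefore judged from the spread between embryos, and no counting interval or floor is given. The 6 libraries differed from each other in every pair, with Pearson r of log2(TPM + 1) between 0.975 and 0.982.

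The authors also deposited 1 comparison table for the series. Per the file headers it holds, for each gene, a base mean (a signal without negative values, which in DESeq2 output is the mean of counts divided by size factors over all libraries), a log2 fold change, its standard error, a Wald score (the log2 fold change divided by its standard error) and the unadjusted and adjusted p-value. The base means sum to 9735035, which describes an average library over the listed genes and not each library. The direction of the fold change and the model are not stated in the authors' table. Its values are given below as the authors', with no recomputed error. Of the 21827 genes, 17605 had a p-value and 14572 an adjusted p-value in the table. Missing adjusted p-values were left missing.

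A count model had been chosen before the data were examined, as had the gene lists, the naming rule and most alternatives. Because the files hold TPM, the comparison of the labelled groups was instead fitted with limma 3.58.1 in R 4.3.3 (moderated linear models with a variance trend and robust moderation) on log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the 6 libraries were kept (12152 genes). A fold change on this scale understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. P-values rest on 3 embryos per label. The smallest p that an exact two-sided permutation test of 3 against 3 libraries can give is 0.1, and none was used for single genes. On simulated data with the means and spreads of these libraries, 71% of 100 genes changed by 1 log2 unit and 88% of 100 genes changed by 2 log2 units were called with the right sign, while 17 unchanged genes were called beside them, more than a rate of 0.05 among calls allows. With no gene changed, 0 were called. The simulated changes followed the labels, which Msx1 contradicts in litters 2 and 3 (see Results). For changes that follow Msx1, these shares overstate what the labelled comparison could detect.

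Gene lists were fixed beforehand, 23 in all: 12 programmes, 7 sets of markers of other cell types, 3 sets that follow RNA handling or metabolic state, and the sex-linked genes, which were not tested. Msx1 and Msx2 are in none of them. Lists were tested against the other genes with camera, using a preset inter-gene correlation of 0.01, and in the authors' table with cameraPR on its Wald scores. Both were repeated with a correlation estimated from the spread within the labelled groups, cameraPR also with the lowest correlation over the 10 splits of the 6 libraries, and the labelled comparison also with fry, counted by its directional p. The programme lists overlap, since Gata3, Hand1, Barx1, Osr2 and Lhx6, for example, each stand in more than 1.

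The genes named for the labelled comparison followed a rule: Msx1, Msx2 and Hand2; the 6 genes with the largest rise and the 6 with the largest fall among genes past the threshold with a mean of at least 1 TPM and the same direction in every litter; and members of the lists. Where too few genes passed, the places went to the genes with the smallest p, given as values. Predicted genes, clone names and pseudogenes were left out. For the authors' table, every gene past its adjusted p of 0.05 is named, and list members with the smallest p; that extension, and the cameraPR test, were chosen after the table was seen.

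The design text states that each litter gave 1 embryo of each genotype, so litter pairs the libraries. Deviations of same-litter libraries from their labelled group means did not vary together, with correlations of -0.0545, -0.0279 and -0.0257 in litters 1, 2 and 3. Of the 6 libraries, 0 correlated best with a littermate. In litters 2 and 3 the labels run against Msx1 (see Results), so these deviations can still hold differences that follow Msx1. The check therefore cannot show whether litter has an effect. The fit with litter as a block is one of the alternatives. Others were the filter, the pseudocount, the scaling of the TPM, the list test, robust moderation and leaving out each library in turn. DESeq2, its size factors and a CPM filter need counts and were not run. The embryos come from separate animals. Gene positions are from GENCODE release M21 on GRCm38, the assembly that mm10 names, joined by gene identifier for 21711 of the 21827 genes.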

Results

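The series compares gene expression in the distal mandible, the tip of the embryonic lower jaw, in embryos with Hand2-Cre. By the labels they are homozygous (mutant) or heterozygous (control) for the floxed homeobox gene Msx1. Both labels are homozygous for floxed Msx2, so the comparison holds no embryo with intact Msx genes. The transcriptomes of 6 libraries were compared, 3 from embryos labelled mutant and 3 from embryos labelled control, in 3 litters of midgestation embryos. Between 11929 and 12132 genes reached 1 TPM in each library. The number of reads behind each value is unknown.

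Msx1, the transcription factor gene whose floxed dose distinguishes the labels (ENSMUSG00000048450, chromosome 5, 37820485 to 37824583, GRCm38), was at 1.90 TPM in the library labelled mutant and 84.1 TPM in the library labelled control of litter 1. The order was opposite in the other litters. Msx1 was at 78.8 TPM in the library labelled mutant and 2.61 TPM in the library labelled control of litter 2, and at 73.3 and 1.99 TPM respectively in litter 3. The targeted gene thus goes against the labels in 4 of the 6 libraries, and directions drawn from the labels below carry that limit. Within litters the higher library exceeded the lower 44.2-fold, 30.2-fold and 36.8-fold. Over the labelled groups the mean was 51.3 ± 42.9 TPM (SD, n = 3) in the mutant label and 29.6 ± 47.2 TPM (SD, n = 3) in the control label, and limma gave a log2 difference of 1.41 ± 1.95 (SE; adjusted p = 0.887).

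**Figure D1:**
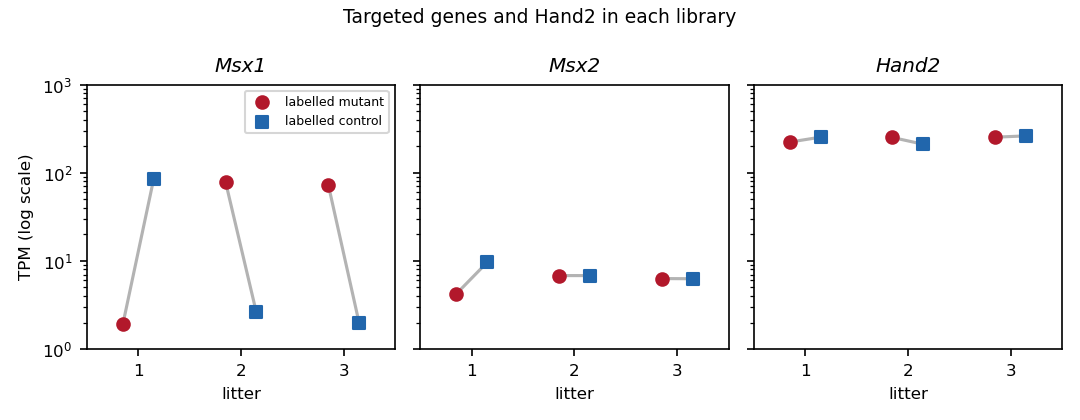
TPM (log scale) of Msx1, Msx2 and Hand2 in each library, by litter; circles are libraries labelled mutant, squares libraries labelled control, and lines join littermates. Msx1 is low at 1.90 TPM in the library labelled mutant of litter 1, and low at 2.61 and 1.99 TPM in the libraries labelled control of litters 2 and 3.

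Msx2, floxed on both copies under either label, was detected at 4.22 to 9.62 TPM in the 6 libraries. The log2 difference between the labels was -0.34 ± 0.21 (SE; limma adjusted p = 0.751). In litter 1 the library labelled mutant had 4.22 TPM against 9.62 TPM in the library labelled control, whereas the littermates of litters 2 and 3 differed by less than 0.1 TPM. Gene-level TPM do not show whether these reads come from the deleted part. Hand2, the gene of the distal arch that gives the Cre driver its name, was at 210.0 to 261 TPM in each library, with a log2 difference of 0.01 ± 0.10 (SE; limma adjusted p = 0.989). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, were at 5.85 to 15.3 TPM in all 6 libraries.

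The comparison table that the authors deposited gives the mutant and control comparison without naming its direction. Msx1 had the smallest p-value in the authors' deposited table, with a log2 fold change of -5.19 ± 0.26 (the table's standard error; adjusted p = 1.97e-84). In all, 14 genes were past an adjusted p of 0.05 in the authors' deposited table. Of these, 5 including Msx1 were negative and 9 positive. Signs are given below relative to Msx1, which was negative in the authors' deposited table, so a positive value means a higher level where Msx1 was lower.

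Among the 9 positive genes of the authors' deposited table were Kcp, Cspg4 and Stk32b. Kcp, which encodes a secreted chordin-like modulator of BMP and TGF-beta ligands (chromosome 6, 29473162 to 29507952), had a log2 fold change of 3.14 ± 0.59 (adjusted p = 0.000332). Its TPM were 4.62, 3.22 and 3.45 in the libraries labelled mutant of litter 1 and control of litters 2 and 3, and 0.783, 0.272 and 0.342 in their littermates. Cspg4, the NG2 proteoglycan gene, had a log2 fold change of 5.10 ± 1.09 in the authors' deposited table (adjusted p = 0.00544), and was listed at 0 in the libraries labelled mutant of litters 2 and 3, at 0.143 TPM in the library labelled control of litter 1, and at no more than 1.07 TPM in any library, so that its fitted fold change is no measure of size. Stk32b, a serine/threonine kinase gene on chromosome 5 (37446825 to 37717171), ends 103 kb from Msx1. It had a log2 fold change of 0.99 ± 0.17 in the authors' deposited table (adjusted p = 7.14e-05), with 23.3, 23.8 and 27.6 TPM in the libraries labelled mutant of litter 1 and control of litters 2 and 3, and 13.1, 12.4 and 12.1 TPM in their littermates.

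The other positive genes of the authors' deposited table were Pgbd1, Adgrl4 (an adhesion receptor gene of endothelium), Adam23, Cttnbp2, Cnot6l (a deadenylase subunit gene) and mt-Co3, with log2 fold changes of 2.81, 2.38, 2.05, 1.80, 0.77 and 0.57. The negative genes besides Msx1 were Reps2, Gria2, Cdk5rap3 and Trim65, with log2 fold changes of -7.39, -4.46, -2.23 and -1.70 in the authors' deposited table. Gria2, a glutamate receptor subunit gene, did not exceed 0.841 TPM in any library, and Reps2 was listed at 0 in the libraries labelled mutant of litter 1 and control of litters 2 and 3 and did not exceed 0.438 TPM in the others, so that its fitted fold change is no measure of size. Of the 14 genes, 9 had a mean below 5 TPM and 3 (Cspg4, Gria2 and Reps2) did not reach 1 TPM in 3 libraries. Of genes with a p-value in the authors' deposited table, 325 (1.85%) had an unadjusted p under 0.05. That is below the share of 0.05 that the threshold alone would give among unchanged genes, so the count shows no excess of small p-values.

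**Figure D2:**
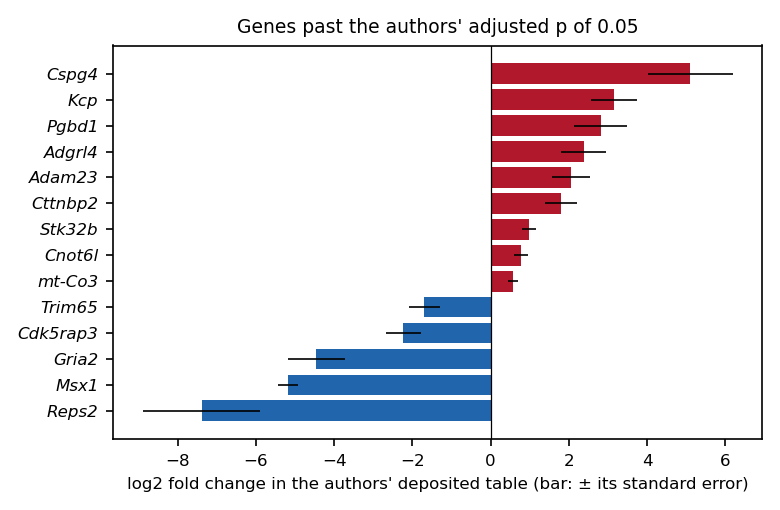
Log2 fold change (horizontal axis) of the 14 genes past an adjusted p of 0.05 in the authors' deposited table; bars are the table's values and lines its standard errors. Msx1 lies at -5.19, 4 other genes share its sign, and 9 genes are positive, the lowest being mt-Co3 at 0.57; the values of Cspg4 (5.10) and Reps2 (-7.39), listed at 0 in some libraries, are no measure of size.

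Most genes of BMP signalling and its targets had the sign of Msx1. Of 25 list members with an adjusted p in the authors' deposited table, 21 were negative and 4 positive, with a median log2 fold change of -0.23. CameraPR on the Wald scores of the authors' deposited table gave an adjusted p of 1.20e-05 for the list, and adjusted p = 0.568 with an estimated correlation. Here and for the lists below, the correlation was estimated within the labelled groups, which mix low and high Msx1 libraries. A shared change with Msx1 would itself raise that estimate, so the larger p cannot show that a list does not follow Msx1. No single member passed the table's threshold or adjustment over the list alone. The members with the smallest p were Gata3, at -0.80 ± 0.29 (p = 0.00636), Smad9, at -0.82 ± 0.35 (p = 0.0205), and Id2, at -0.33 ± 0.15 (p = 0.0288), all unadjusted values from the authors' deposited table. Bmp4, the ligand gene expressed in distal arch tissue, was at -0.23 ± 0.17, and the BMP-responsive genes Id1, Id3, Hand1 and Tbx2 were at -0.24, -0.22, -0.33 and -0.33 in the same table. The receptor genes Bmpr1a and Bmpr2 were at -0.005 and 0.02, and the inhibitory Smad7 at -0.002. The positive members besides Bmpr2 were Chrd, Gata2 and Bmp7, at 1.79 ± 2.07, 0.13 ± 0.33 and 0.04 ± 0.25. Chrd was listed at 0 in some libraries and did not exceed 0.612 TPM in any, so that its fitted fold change is no measure of size. Grem1 and Fst, which like Chrd encode BMP antagonists, were at -0.97 ± 0.57 and -0.20 ± 0.62. The list joins antagonists with ligands, receptors and targets, so its median gives no direction of BMP signalling. The mean log2(TPM + 1) of the BMP list was 3.97 in the library labelled mutant and 4.29 in that labelled control of litter 1, 4.19 and 3.98 in litter 2, and 4.14 and 4.06 in litter 3. The library labelled control of litter 1, which gives the widest gap, also had the highest mitochondrial share (8.03%).

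**Figure D3:**
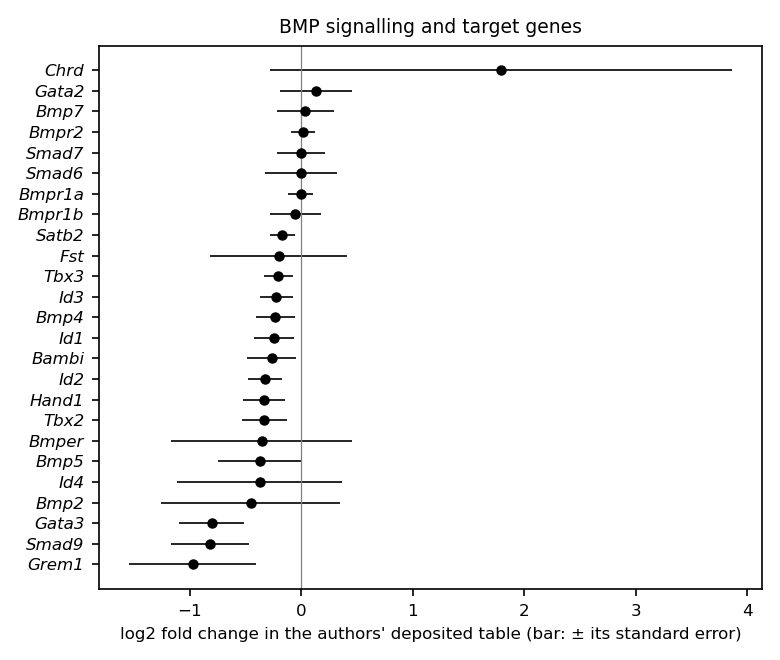
Log2 fold change (horizontal axis) of the 25 genes of the BMP list with an adjusted p in the authors' deposited table; points are the table's values and lines its standard errors. Of the 25, 21 lie below 0, with Gata3 at -0.80 and Smad9 at -0.82, and none passes the table's threshold.

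Markers of embryonic red blood cells were higher in the authors' deposited table, with a median log2 fold change of 0.55 and a cameraPR adjusted p of 2.97e-05 (adjusted p = 0.568 with an estimated correlation). The embryonic globin genes Hbb-bh1 and Hbb-y were at 0.94 ± 0.80 and 0.54 ± 0.66, neither past the threshold. The 13 marker genes held 3.07% of the listed TPM in the library labelled mutant of litter 1 and 0.963% to 1.32% in the other 5 libraries. Hypoxia and glycolysis genes were lower in the authors' deposited table, with 13 of 17 negative, a median of -0.16 and a cameraPR adjusted p of 0.00313 (adjusted p = 0.568 with an estimated correlation). Bnip3, a mitophagy gene induced in hypoxia, was at -0.44 ± 0.24 and Aldoa, a glycolytic enzyme gene listed on 2 rows, at -0.18 ± 0.12 on the higher-expressed row and 0.82 ± 2.08 on the other. Mitochondrially encoded transcripts were lower, with 11 of 13 negative, a median of -0.12 and an adjusted p of 0.0133 (adjusted p = 0.568 with an estimated correlation). One member, mt-Co3, passed the threshold of the authors' deposited table with the opposite sign, at 0.57 ± 0.13. Mitochondrial transcripts held 8.03% of the listed TPM in the library labelled control of litter 1 and 6.02% to 6.51% in the other 5 libraries.

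The other programme lists did not pass the cameraPR test in the authors' deposited table. The endothelin, Dlx and Hand genes that specify the distal jaw had 10 of 16 negative (adjusted p = 0.158), with Dlx5 at -0.15 ± 0.12, Rgs5 at -0.36 ± 0.18 and Hand2 at -0.13 ± 0.11. In the list of proximal and intermediate arch patterning, 10 of 19 were positive (adjusted p = 0.447). Of such lists, 3 members passed when adjusted over the list alone, and none over all genes tested by the authors. They were Nr2f2, a nuclear receptor gene of the more proximal arch, at 0.65 ± 0.19, Foxd1, a forkhead gene among hedgehog targets, at 0.71 ± 0.22, and Fgfr1 at 0.50 ± 0.15 in the authors' deposited table. Nr2f2 hardly differed in litter 2, at 66.3 TPM in the library labelled mutant and 67.1 TPM in that labelled control. It was at 64.0 and 36.5 TPM respectively in litter 1, and at 42.6 and 92.1 TPM in litter 3. Barx1, a homeobox gene of arch mesenchyme and molar fields, was at 0.38 ± 0.14 (unadjusted p = 0.00871), and did not pass over its list. Osteogenesis genes had 8 of 13 positive (adjusted p = 0.454) with Col1a2 at 0.25 ± 0.11, WNT genes 16 of 29 positive (adjusted p = 0.891) with Rspo2 at -0.48 ± 0.21, and tooth mesenchyme genes 11 of 17 negative (adjusted p = 0.607). Cell cycle genes had 20 of 30 positive (adjusted p = 0.607), chondrogenesis genes 8 of 15 negative (adjusted p = 0.891) and p53 targets 11 of 19 positive (adjusted p = 0.891). Alx, Pax, Pitx, Prrx and Tfap2 genes had 8 of 14 negative (adjusted p = 0.607), hedgehog genes 12 of 20 negative (adjusted p = 0.671) and FGF genes 9 of 18 negative (adjusted p = 0.891).

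Markers of the other cell types in the tissue did not pass either in the authors' deposited table. CameraPR on the Wald scores gave an adjusted p of 0.891 for epithelium, 0.445 for skeletal muscle progenitors, 0.683 for neurons, 0.891 for glia, 0.683 for endothelium and 0.891 for macrophages. Immediate early and heat shock genes, which respond to dissection, had an adjusted p of 0.891.

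The comparison by the labels as deposited called no gene. Of 12152 genes tested with limma, 0 were higher and 0 lower in the libraries labelled mutant at an adjusted p of 0.05, and the smallest adjusted p was 0.458. At an unadjusted p under 0.05 there were 231 genes with positive and 586 with negative differences, a split that became 410 and 305 after median-of-ratios scaling. With litter as a block the count was also 0, with 258 and 512 genes at an unadjusted p under 0.05. No count model was run, since the values are TPM.

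The genes with the smallest p in the labelled comparison are given as values. Those higher in the libraries labelled mutant were Atxn1l, Rps29, Krt14, Hist1h4n, Wdr83 and Pigx. Their log2 differences were 0.72, 0.43, 1.06, 0.90, 0.94 and 0.55, with limma adjusted p between 0.489 and 0.669. Krt14, a keratin gene of basal epithelium, was at 4.63 ± 0.59 TPM (SD, n = 3) in the libraries labelled mutant and 1.72 ± 0.50 TPM (SD, n = 3) in those labelled control. It was the only 1 of 18 epithelial markers to pass when adjusted over the list alone. Of the 18, only 6 were positive, with a median log2 difference of -0.13 (camera adjusted p = 0.762). The genes with the smallest p among those lower in the libraries labelled mutant were Fam13b, Efcab7, Duxbl2, Iah1, Atp10d and Jagn1. Their log2 differences were -0.71, -1.17, -1.34, -0.65, -0.54 and -0.45, with limma adjusted p of 0.458 or 0.489. Among programme members, Fgfr2 was at -0.37 ± 0.09, Sox5 at -0.50 ± 0.12, Meis2 at -0.29 ± 0.10 and Osr2 at 0.94 ± 0.30 (SE), and none passed limma's threshold over all genes, with adjusted p of 0.669 to 0.686. Sox5, a cartilage transcription factor gene, passed over the chondrogenesis list alone, as did mt-Co1 over the mitochondrial list.

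Of the 22 lists tested, camera called 1 between the labelled groups. The 12 tested red blood cell markers were all higher in the libraries labelled mutant, with a median log2 difference of 0.41. The camera adjusted p was 0.000110 (adjusted p = 0.881 with an estimated correlation). Without the library labelled mutant of litter 1 the median was -0.06 and the list was not called (adjusted p = 0.888). The BMP list, lower in the authors' deposited table, had 11 of 21 members positive and a median of 0.007 between the labelled groups (camera adjusted p = 0.762).

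None of the 14 genes of the authors' deposited table was called in the labelled comparison, which tested 11 of them. With the labels of litters 2 and 3 exchanged, limma called Msx1 and no other of the 11 tested genes. Cspg4, Gria2 and Reps2 did not reach 1 TPM in 3 libraries, so they could not be called under either grouping. In the exchanged grouping 3 gene lists were called, against 1 in the labelled grouping and up to 4 in other splits of the 6 libraries. Which lists the exchanged grouping called is not given here. Across 12152 genes the log2 differences of the labelled comparison and the fold changes of the authors' deposited table had a Pearson r of -0.23 and a Spearman rho of -0.32; leaving out 1 library at a time gave a Pearson r from -0.51 (without labelled mutant of litter 1) to -0.09 (without labelled control of litter 3). Both come from the same libraries, and genes are not independent replicates.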

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

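Among the tests in this part, the pseudocount, the 5 TPM mean, the 3 scalings and all alternatives of the authors' table were chosen after the data were seen. The count of 0 genes higher and 0 lower held under every setting run except 2 that left out 1 library. Leaving out each library in turn gave 0 to 1 gene higher (Gm5244, without the library labelled control of litter 1) and 0 to 1 lower (Rpl29, without that labelled mutant of litter 1). Calls shared with the authors' table stayed at 0. The replicate block (litter as paired term) gave 0 genes higher, 0 lower and 1 list, and changed no other call. The count of 1 gene list became 0 with an estimated correlation, 0 with fry's directional p (its mixed p, for change in either direction, passed for oral and surface epithelium, adjusted p 0.000205), 2 with quantile normalization, and 0 to 3 when leaving out each library: 0 without the library labelled mutant of litter 1, and 3 without labelled mutant of litter 2 or labelled control of litter 3. The Msx1 difference stayed positive and uncalled, from 0.56 to 2.99 over the left-out libraries. The correlation with the authors' fold changes moved from -0.23 to -0.51 without the library labelled mutant of litter 1 and to -0.50 without that labelled control of litter 1, and lay between -0.12 and -0.09 without any 1 library of litters 2 and 3. Hand2, at 0.01, ranged from -0.0894 (without labelled control of litter 2) to 0.0682 (without labelled control of litter 3) and was also negative without labelled mutant of litter 2 (-0.0189) or 3 (-0.0250), uncalled throughout. Of 535 values of 36 named genes other than Msx1 and Msx2, 532 kept direction and side of the threshold; the 3 reversals are those of Hand2. With the authors' p-values adjusted over genes with a base mean of at least 50, 9 genes passed in place of 14. Gria2, Kcp, Reps2, Cspg4 and Adgrl4, with base means of 30.9, 46.3, 15.2, 23.9 and 43.4, were removed by that cut. The 4 lists of the authors' table became 0 with an estimated correlation. They became 1 (BMP) with the lowest correlation over the splits, the most lenient of the estimates. They stayed 4 with ranks, with base means of at least 50 and without the called genes. Except for the genes removed by the base mean cut, the cause of these changes was not tested. A fit without litters 2 and 3, whose labels Msx1 contradicts, leaves 1 library per group and no test. DESeq2, its size factors and a CPM filter were not run for lack of counts. Depth limits are unknown, since TPM carry no counts.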

Other observations

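Among the tests in this part, the test of Cre escape, those of endothelial and red blood cell share, and the count of splits for genes were chosen after the result was seen.

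Single members of the programme lists, the BMP list included, had fold changes of both signs in the authors' table. Nr2f2, Foxd1, Fgfr1 and Barx1 were positive at 0.65, 0.71, 0.50 and 0.38, while Grem1, Gata3, Rspo2 and Dkk1 were negative at -0.97, -0.80, -0.48 and -0.47. None of these passed the authors' threshold, and they were chosen after their values were seen.

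The first pattern is Msx1, whose level in litters 2 and 3 is opposite to the labels. One hypothesis is that mutant and control labels were exchanged within those litters, either in the sample titles or in the files. The authors' fold changes were compared with each of the 10 ways to split the 6 libraries, leaving Msx1 out. The split that exchanges litters 2 and 3 gave a Pearson r of 0.85 across 12151 genes, the highest other split gave 0.35 in size, and the labelled split gave -0.23. This is consistent with an exchange, and each low library has a high littermate as partner. That Cre failed in the labelled mutants of litters 2 and 3 is argued against by their littermates: the libraries labelled control, which should keep 1 allele, had at most 3.10% of the Msx1 of the library labelled control of litter 1. Whether the titles or the files hold the exchange stays open.

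The labelled split called 0 genes and the highest of the other splits 1. Any split gives at least 0 genes, so the count of 10 of 10 splits with as many was fixed by the 0 and carries no information. The labelled split called 1 list and the highest other 4, and 8 of 10 splits gave as many. With 10 splits there are too few for a share under 0.05. Of the splits, 4 part all 3 litters: the labelled one and 3 others, which called 0, 1 (Rps27rt) and 1 (Msx1) genes, with the same counts when litter was a block. The last of these is the split that exchanges litters 2 and 3.

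The second pattern is the lower BMP list in the authors' table, for which a role of Msx1 upstream of BMP genes is a biological hypothesis that was not tested here. Dilution by red blood cell RNA is argued against. It lowers other transcripts alike, and scaling shifts all lists by the same amount, but the median of the BMP list (-0.23, 95% bootstrap interval -0.33 to -0.05) lay below that of 189 members of the other programme lists (0.01) by a difference of -0.246 (interval -0.352 to -0.0761; genes were resampled as independent). The measured red blood cell shares change the other transcripts of the library labelled mutant against its littermate by -0.0311, 0.0036 and -0.0026 log2 units in litters 1, 2 and 3. In litters 2 and 3 the library with low Msx1 is the one labelled control, so read by Msx1 these signs turn. Litters 1 and 2 then go with dilution and litter 3 goes against it, each by less than the median of the BMP list. A smaller endothelial share cannot be told apart, since the endothelial median was -0.0625 and its interval, -0.19 to 0.09, overlaps. Genes varying together may also account for the small p, with an adjusted p of 0.568 when the correlation was estimated within the labelled groups. That estimate also holds any difference between low and high Msx1 libraries. With the lowest correlation over the 10 splits, the cameraPR adjusted p was 0.0315 for the BMP list. Those of red blood cells (0.427), hypoxia and glycolysis (0.260) and mitochondrial transcripts (0.427) missed the threshold. The lowest of 10 estimates for a list (0.0861 for BMP, against 0.304 within the labelled groups) is the most lenient of them. Its small p therefore cannot count against genes varying together, and this stays open too. By the prediction written before the test, the adjusted p of 0.568 alone would have counted for the explanation. The use of the lowest correlation was added after the result was seen.

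The third pattern is Stk32b, which lies 103 kb from Msx1 and had the opposite sign in the authors' table. A candidate explanation is that DNA around Msx1 differs between the groups, as flanking sequence of the floxed allele or through the deletion itself. Of 78 other genes within 5 Mb of Msx1, 1 had an unadjusted p under 0.05 (1.28%), against 321 of 17479 elsewhere (1.84%; Fisher's exact test, two-sided, p = 1; odds ratio 0.694, 95% interval 0.0173 to 4.01). The interval is too wide to exclude an effect confined to few neighbours. By the prediction written before the test the result would have counted against the explanation; the demand on the interval was added after the result was seen. As it stands, this and a response of Stk32b to Msx1 cannot be told apart.

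The red blood cell list was higher in the authors' table and in the labelled comparison with the preset correlation and in neither with an estimated one (adjusted p 0.568 and 0.881). Without the library labelled mutant of litter 1 the labelled median was -0.06. The library labelled mutant of litter 1, with 3.07% of its TPM in those genes, is on the same side in both comparisons. Among genes with a base mean of at least 100, 2.30% had an unadjusted p under 0.05 in the authors' table, which is also below a share of 0.05.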
